A study of Mus musculus with 6 samples.

How the data were processed

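Whole livers of embryos at embryonic day 12.5 were dispersed to single cells, and their RNA was extracted with Trizol and sequenced as standard Illumina libraries, per the labels. The labels give 3 wild-type livers (numbers 2, 15 and 17) and 3 livers with the E861A mutation of ADAR1 (numbers 6, 16 and 19), with the sex of each. No paired analysis was possible because the genotypes share no replicate number and the labels name no litter. Per the submitters' processing notes, Trimmomatic (0.30), TopHat2 (2.0.8), Bowtie2 (2.1.0.0), SAMtools (0.1.19), BWA, HTSeq, Cufflinks, edgeR and limma were used with the mouse builds mm9 and NCBIM37. The notes do not tie these tools to a file or an order.

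The gene table holds raw counts as deposited by the authors, whole numbers of reads for each of 37576 Ensembl genes in 6 libraries. The site table holds, per the file headers, the number of covering reads and the editing level as a fraction of those reads for each site and library, both as deposited by the authors. It also holds the authors' mean levels and a p-value per site whose column name, per the file headers, is that of an analysis of variance. The third table holds the authors' log2 fold changes and p-values for each gene as deposited, in columns named as limma names them, per the file headers. Its fold changes are wild type minus mutant per the file headers, and the sign was turned here. The table of normalised counts was not used, since its values are the raw counts times 1 constant per library. Whether the libraries were stranded is not stated, so overlapping and antisense genes such as Cxcl11 (annotated as antisense) may hold reads of a neighbour.

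Reads counted in genes were 39441790, 43733715 and 39192271 in wild type 2, 15 and 17, and 42141482, 35280460 and 43080042 in E861A 6, 16 and 19. Replicates of a genotype differed from each other by far more than counting error, with a chi-square per degree of freedom from 40.3 to 125.4 between pairs. The Pearson correlation of log2 CPM between replicates was 0.964 to 0.990. Counting intervals and floors, where given, cover counting error only.

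Gene expression was compared with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 16511 genes, TMM factors scaled the libraries, and the robust quasi-likelihood fit and F test compared E861A with wild type. Positive log2 fold changes are higher in E861A. A gene changed where the Benjamini-Hochberg adjusted p over all tested genes was under 0.05. CPM are counts scaled to 1e6 reads by TMM-scaled totals, SD is across 3 libraries, and SE is the log2 fold change over the square root of F. A gene with no read in a genotype is given as at least N-fold against a floor of 3 counts over that genotype, and one with 1 to 3 reads as a ratio with a counting interval at 95%. Gene positions and types are those deposited with the counts. GENCODE M1, used here to annotate sites, held 37205 of the counted genes, 99.3% of them with the same start. All positions are in NCBIM37.

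A total of 20 gene lists was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, with the estimated correlation as an alternative and fry beside it, adjusted by Benjamini-Hochberg over the 20. The pathway lists were interferon-stimulated genes, interferon induction and signalling, RNA editing and double-stranded RNA binding, p53 targets and apoptosis, unfolded protein and integrated stress response, cell cycle, and haem synthesis and iron handling. The cell lists were erythroid cells, embryonic globins, stem and progenitor cells, macrophages and monocytes, granulocytic cells, megakaryocytes, lymphoid cells, hepatoblasts, endothelial cells, mesenchymal and stellate cells, and dissociation and RNA quality. The last 2 lists, genes with any tested site and genes with a lower site, were made from these samples. Members without a match in the table (such as Ifit3b, Ifi27 and Spi1) or with too few reads for the filter were not tested.

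The site table holds 6012 sites, and the reference base of each matched NCBIM37. Edited reads were the level times the coverage, which lay within 2e-06 of a whole number at each site. Sites with at least 10 reads in each genotype, 3883 of them, were compared by a two-sided Fisher's exact test on edited and unedited reads summed per genotype, with Benjamini-Hochberg adjustment, in Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3 and NumPy 2.4.6. The other 2129 sites had fewer reads and were left out. Levels are in percent with Wilson intervals at 95%, and a level of 0 over the summed E861A reads is given with the level that 3 edited reads would have. Mean levels over sites are per library, compared by an exact permutation test, which with 3 libraries against 3 cannot go below 0.10. The sites of 2 editing lists, recoding substrates and the 3' duplexes of Klf1, Oip5 and Optn, were followed by name. The second list was taken from earlier published work on this mutant, so it may rest on related material and is not an independent choice.

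These choices, the lists of genes and the rule for naming genes were made before the data were examined. The rule named Adar and Ifih1, Xist and 4 genes of the Y chromosome, then the 10 largest rises and the 10 largest falls. For these a gene had to change, have 3 libraries of a genotype all above the other 3, and reach a mean of 1 CPM in the higher genotype. From each fixed list the 3 measured members with the smallest p were named. For sites it named the 10 largest differences in level with at most 1 site per gene and the best covered site of each gene on the editing lists. Genes and sites named outside the rule are said to be so. Some sites that the rule names are not reported here, though they stay in the counts.

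The alternatives set beforehand were DESeq2 (1.42.0) size factors or library totals for scaling, no filter or 1 CPM in 3 libraries as the filter, DESeq2 or limma voom as the test, sex as a covariate, no genes of the X and Y chromosomes, male libraries only, and each library left out in turn. With male libraries only the single wild-type library is assumed to vary like the E861A libraries. For sites they were a minimum of 5 or 20 reads, only sites at 10% or more in wild type, and a quasi-binomial model across libraries. Chosen after seeing the data were covariates for the range of the embryo numbers and for the mean level of the mesenchymal and dissociation lists, sites with at least 10 reads in every library, sites without those at 90% or more in both genotypes, and a quasi-binomial model with 1 dispersion for all sites.

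The tests were tested on simulated data with the depth of these libraries. The edgeR test found 37 of 100 genes changed by 2-fold and 88 of 100 changed by 4-fold, and 9 of its calls (6.7%) were false. With camera, 1 of 50 lists of unchanged genes had a p under 0.05. Fisher's test found 87.7% of sites that lost a level of 40% and 46.7% of those that lost a level of 10%, with 3 false calls. Absence of a call is therefore weak evidence for changes of 2-fold or less. The simulated genes varied independently of each other, and the simulated reads at sites had no spread between libraries beyond counting. The false calls found there therefore do not cover correlation between genes or spread of editing between libraries.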

Results

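Fetal livers of C57BL/6 mouse embryos at embryonic day 12.5 were dissociated into single cells, and RNA of the whole suspension was sequenced. At this age the liver holds mostly red cell precursors, together with blood progenitors, macrophages, hepatoblasts, endothelial cells and mesenchymal cells. ADAR1, encoded by Adar, converts adenosine to inosine in double-stranded RNA, and inosine is read as G after sequencing. In the E861A mutant a single residue of the enzyme is replaced and the protein cannot edit. The wild-type group held livers 2 (male), 15 and 17 (both female), and the E861A group held livers 6, 16 and 19 (all male), so that sex was partly tied to genotype. Reads counted in genes ranged from 35280460 in E861A 16 to 43733715 in wild type 15. The comparison of the genotypes asks what the absence of ADAR1 editing changes in the fetal liver transcriptome, and which sites lose editing.

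Adar itself (ENSMUSG00000027951, chromosome 3, starting at 89518944) was higher in each E861A library than in each wild-type library. Its level was 64.3 ± 12.7 CPM in wild type and 317.7 ± 37.5 CPM in E861A (SD, n = 3 each), a log2 fold change of 2.30 (SE 0.19). As a single residue is mutated, this level does not check the genotype labels. Ifih1, which encodes a cytosolic sensor of double-stranded RNA, rose from 11.2 ± 1.93 to 237.8 ± 52.1 CPM, a log2 fold change of 4.40 (SE 0.23). Both passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.00026 for Adar and 2.13e-05 for Ifih1). The sex labels matched the reads. Xist stood at 1234 and 1189 CPM in the female libraries and at most 1.23 CPM in the male ones. The Y-linked gene Ddx3y stood at 87.8 CPM in wild type 2 and from 98.2 to 103.4 CPM in E861A, against at most 0.08 CPM in the female libraries, and Eif2s3y, Uty and Kdm5d followed the same split.

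Loss of ADAR1 editing went with a broad interferon response. Of 16511 genes tested, 1986 changed, of which 1283 rose and 703 fell in E861A. The rises were larger, with 459 genes rising and 16 falling by more than 4-fold as fitted. The 10 largest rises among genes of at least 1 CPM were in Ifi44, Apol9a, Tgtp1, Tgtp2, Cxcl11, Apol9b, Oas3, Gm8696, Pydc4 and Oas1g, most of them known interferon targets. Ifi44 rose from 0.146 ± 0.066 to 194.9 ± 49.97 CPM (SD, n = 3 each) and Oas3, a sensor of double-stranded RNA that makes the activator of RNase L, from 0.395 ± 0.179 to 258.1 ± 26.4 CPM. The chemokine gene Cxcl11 and the pseudogene Gm8696 had no read in wild type, and against a floor of 3 reads over the group they were at least 101-fold and 71-fold higher in E861A. Apol9a had 2 reads in wild type, giving a ratio of 1450 with a lower counting bound of 400. Tgtp1 and Tgtp2, Apol9a and Apol9b, and the members of the Oas1 family are near-identical copies, so how their reads divide among them is uncertain.

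The 10 largest falls were smaller in size. They were in Ccr9 (log2 fold change -3.83, SE 0.64), the long non-coding RNA Gm13881 (-3.21, SE 0.51), Ccl24 (-2.86, SE 0.59), Aknad1 (-2.54, SE 0.35), Mgll (-2.39, SE 0.22), Fcrls (-2.38, SE 0.60), Pkd1l1 (-2.25, SE 0.35), Phyhip (-2.24, SE 0.43), Snx22 (-2.14, SE 0.22) and Myo15 (-2.14, SE 0.39). Mgll, which encodes monoacylglycerol lipase, went from 59.1 ± 14.4 to 11.3 ± 1.84 CPM, and Snx22, a sorting nexin, from 46.4 ± 13.2 to 10.5 ± 0.93 CPM (SD, n = 3 each). Mgll and Snx22 also passed with sex in the model and in male libraries alone, Aknad1 only with sex in the model, Gm13881 only in male libraries, and the other 6 in neither.

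Of 14484 genes in the authors' deposited table, 1222 were higher and 701 lower in E861A at an adjusted p under 0.05. Of these, 1813 were called in the same direction here. The counts depended on sex and on the tool: 530 genes rose and 39 fell with sex as a covariate, 301 rose and 8 fell in the male libraries alone (1 of them wild type), 1160 fell when genes needed 1 CPM in 3 libraries and 1388 fell with DESeq2. They depended on single libraries too, with 795 rises and 197 falls without wild type 15, 555 and 95 without wild type 17, 515 and 150 without E861A 16, and 1737 and 1502 without wild type 2.

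**Figure D1:**
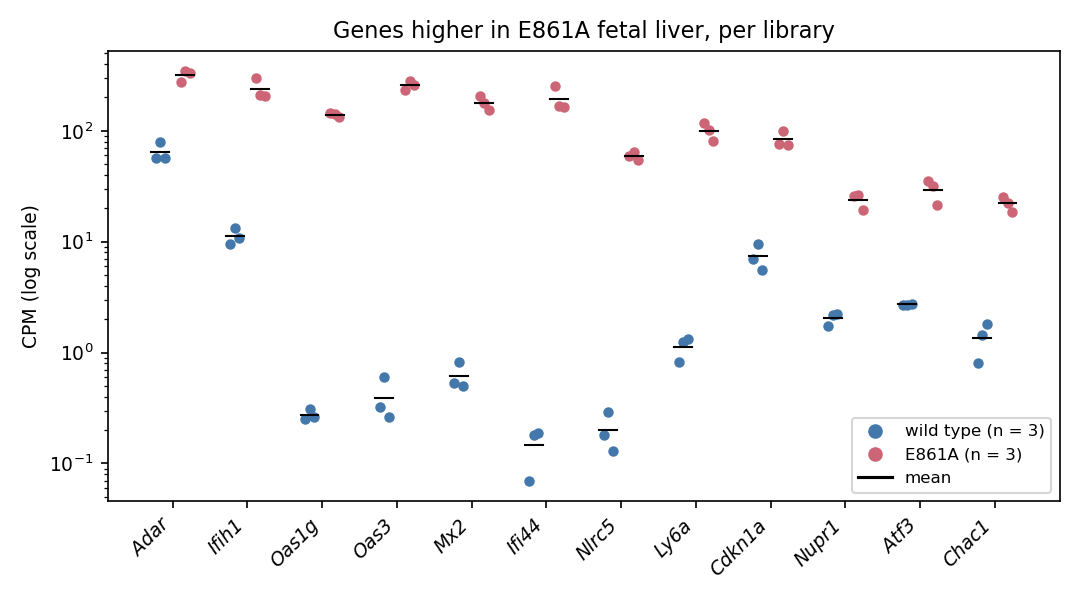
Scaled read counts (CPM, log scale) of 12 genes in each library, wild type in blue and E861A in red, with 1 point per library and a black line at the mean of 3. Each E861A library lies above each wild-type library, from 64.3 to 317.7 CPM on average for Adar and from 0.395 to 258.1 CPM for Oas3.

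Interferon-stimulated genes moved further than any other fixed list. All 62 measured members lay above 0 in log2 fold change, and 61 rose over all genes tested and 62 when adjusted over the list alone, with a median of 5.38. The member that did not pass over all genes was Ube2l6 (0.88, SE 0.34). By the smallest p the leading members were Oas1g (8.96, SE 0.19), the regulator of MHC class I genes Nlrc5 (8.18, SE 0.26) and the antiviral GTPase Mx2 (8.17, SE 0.26), and Mx2 rose from 0.622 ± 0.184 to 179.1 ± 25.2 CPM (SD, n = 3 each). The list passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 3.68e-65). That call was lost at adjusted p = 0.221 with an estimated correlation. Genes that sense nucleic acid or induce and signal interferon moved less, with 11 of 24 rising and 1 falling (15 and 1 when adjusted over the list alone) and a median of 0.60. Among them were the endosomal receptor Tlr3 (4.27, SE 0.32), the kinase Ikbke (1.82, SE 0.16) and the NF-kB inhibitor Nfkbia (1.84, SE 0.17). The member that fell was the adaptor Mavs (-0.77, SE 0.20), named after its value was seen. So were the interferon genes Ifnb1, with 1 read in wild type and 285 in E861A, and Ifna4, with 0 and 107 reads, and Ifna4 has near-identical copies that leave its value uncertain. Its camera adjusted p was 6.71e-07, against adjusted p = 0.499 with an estimated correlation.

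Stress genes rose as well. Of 23 p53 targets and apoptosis genes 12 rose and none fell (16 when adjusted over the list alone), with a median of 0.97. The cell cycle inhibitor Cdkn1a went from 7.36 ± 1.98 to 83.8 ± 14.1 CPM (SD, n = 3 each; log2 fold change 3.51, SE 0.24). Mlkl, the executor of necroptosis, rose by 3.86 (SE 0.29) and the p53-induced receptor Eda2r by 3.27 (SE 0.29). Of 23 genes of the unfolded protein and integrated stress responses 14 rose and none fell (17 when adjusted over the list alone), with a median of 0.95, led by Nupr1 (3.55, SE 0.22), Atf3 (3.43, SE 0.23) and Chac1 (4.04, SE 0.32). Camera gave adjusted p = 2.46e-08 for the p53 list and 6.62e-10 for the stress list, against adjusted p = 0.206 and 0.533 with an estimated correlation. Immediate-early and heat shock genes that respond to tissue dissociation moved with these lists. Of 12 such genes 7 rose and none fell (9 when adjusted over the list alone), with a median of 1.38, including Egr1 (1.84, SE 0.23), Hspa1a (4.54, SE 0.69) and Btg1 (0.80, SE 0.15). Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. The mean level of the dissociation list was 2.95, 4.97 and 4.54 log2 CPM in wild type 2, 15 and 17 and 5.07, 6.46 and 6.37 in E861A 6, 16 and 19. Its camera adjusted p was 5.85e-05, against adjusted p = 0.533 with an estimated correlation. In the p53 list 7 genes rose without E861A 16 and 6 in male libraries alone, in the stress list 9 without wild type 17 and 7 with sex as a covariate, and in the dissociation list 1 without wild type 17 and 2 without E861A 16.

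**Figure D2:**
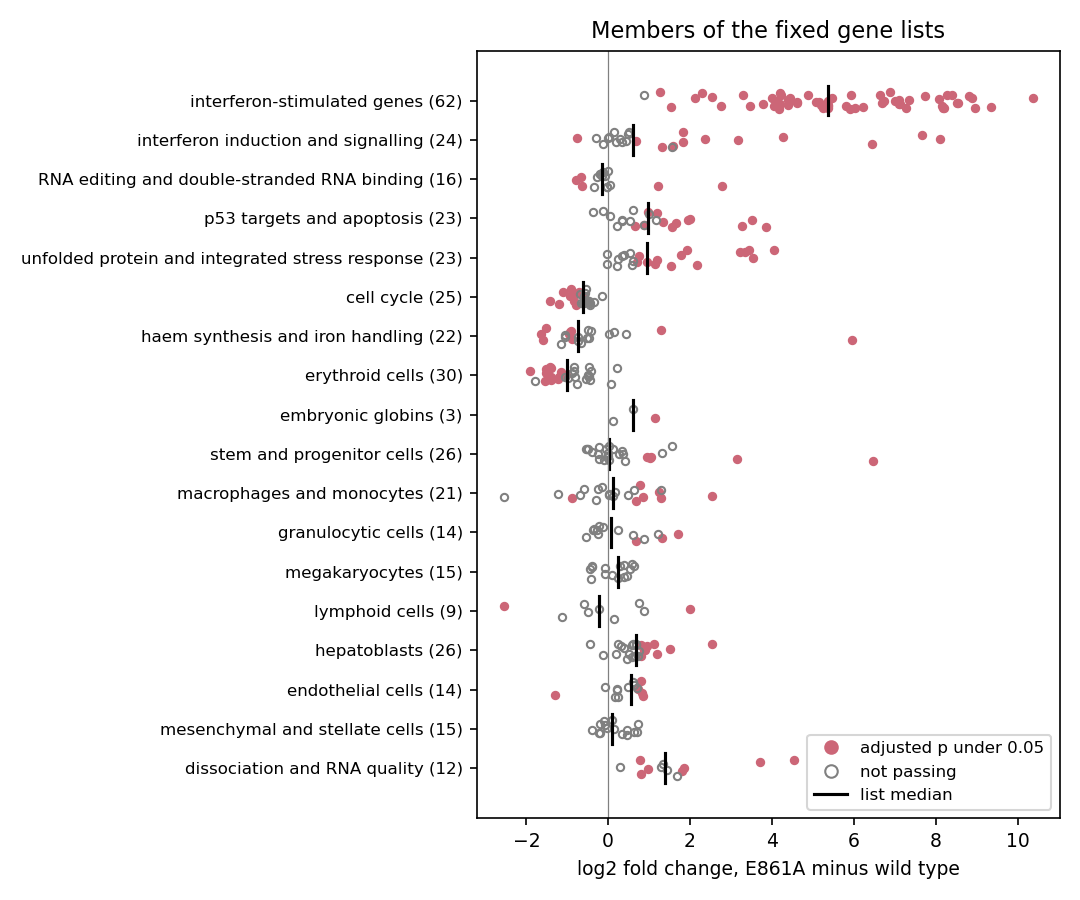
Log2 fold change (E861A minus wild type, horizontal axis) of each measured member of the 18 gene lists fixed beforehand, with the number of members in brackets, filled red where the adjusted p was under 0.05, open where it was not, and a black bar at the list median. The interferon-stimulated genes have a median of 5.38, and the medians of the other 17 lists lie between -1.01 and 1.38.

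Red cell genes were lower in E861A. Of 30 erythroid genes 13 fell and none rose (19 when adjusted over the list alone), with a median of -1.01. The anion exchanger of the red cell membrane, Slc4a1, fell from 4764 ± 2042 to 1259 ± 85.1 CPM (SD, n = 3 each; log2 fold change -1.92, SE 0.30). The membrane protein gene Epb4.2 fell by 1.54 (SE 0.25) and the tropomodulin gene Tmod1 by 1.43 (SE 0.25) on the log2 scale. Of 22 genes of haem synthesis and iron handling 7 fell and 2 rose (15 and 2 when adjusted over the list alone), with a median of -0.74. Fech, the enzyme that inserts iron into haem, fell from 989.8 ± 345.4 to 327.3 ± 72.5 CPM and the ferrireductase Steap3 from 159.9 ± 46.9 to 56.0 ± 11.9 CPM. The members that rose were Hamp, the gene of the iron hormone hepcidin, with 3 reads in wild type and 216 in E861A (ratio 69.8 with a lower counting bound of 23.6), and Hmox1, the haem-degrading oxygenase (1.28, SE 0.24). Of 25 cell cycle genes 10 fell and none rose (24 when adjusted over the list alone), with a median of -0.62. They included the ribonucleotide reductase subunit Rrm2 (-1.42, SE 0.20; 642.7 to 239.7 CPM) and the cyclins Ccna2 (-1.10, SE 0.23) and Ccnb1 (-0.84, SE 0.18). Embryonic globins did not follow the erythroid list: Hba-x rose from 1661 ± 581 to 3642 ± 303 CPM (1.13, SE 0.25), while Hbb-y (0.60, SE 0.17) and Hbb-bh1 (0.12, SE 0.27) did not pass. Adjusted over the list alone 2 of the 3 rose, and the median was 0.60.

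Camera gave adjusted p = 5.38e-10 for the erythroid, 9.63e-05 for the haem and iron and 1.01e-10 for the cell cycle list, against adjusted p = 0.533, 0.537 and 0.533 with an estimated correlation, and 0.108 for the embryonic globins, which passed with sex as a covariate (0.0165) and in the male libraries alone (0.00515). Wild type 2, the male wild-type library, lay nearest to E861A, at a mean of 8.62 log2 CPM over the erythroid list against 9.63 and 9.03 in wild type 15 and 17 and 8.24, 8.19 and 8.06 in E861A 6, 16 and 19. With sex as a covariate edgeR called none of the 30 erythroid genes (medians -1.01 without and -0.45 with sex), none of the falls in the haem and iron list (median -0.39) and 1 of the 25 cell cycle genes (median -0.31). Leaving out wild type 2, 15 or 17 or E861A 6, 16 or 19 gave 21, 9, 5, 8, 4 and 8 falling erythroid genes, 20, 1, 1, 8, 1 and 6 falling cell cycle genes, and 13, 3, 2, 4, 0 and 3 falling haem and iron genes, in that order. The dissociation list, higher in E861A, and the mesenchymal list, at 6.24 log2 CPM in wild type 2 against 4.58 and 5.38 in wild type 15 and 17, moved with these libraries as well.

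**Figure D3:**
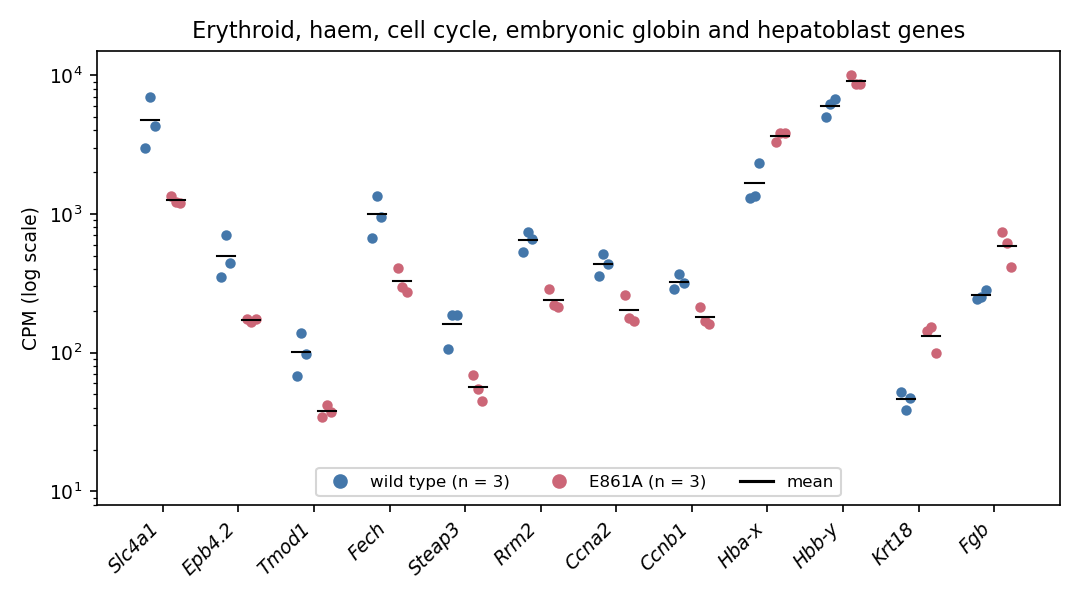
Scaled read counts (CPM, log scale) of erythroid, haem, cell cycle, embryonic globin and hepatoblast genes in each library, wild type in blue and E861A in red, with a black line at the mean of 3 libraries. Slc4a1 averaged 4764 CPM in wild type and 1259 CPM in E861A, while Hba-x averaged 1661 and 3642 CPM.

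Among the other cell types of the liver, hepatoblast genes were higher in E861A. Of 26 hepatoblast genes 10 rose and none fell (19 rose and 1 fell when adjusted over the list alone), with a median of 0.69. Krt18, a keratin of epithelial cells, rose from 46.1 ± 6.92 to 131.4 ± 28.6 CPM, the fibrinogen chain gene Fgb from 258.6 ± 19.9 to 590.0 ± 165.1 CPM (SD, n = 3 each). The transcription factor gene Cebpb rose by 2.55 (SE 0.22) on the log2 scale. Of 14 endothelial genes 4 rose and 1 fell (8 and 1 when adjusted over the list alone), with a median of 0.55. Ramp2 (0.81, SE 0.15) and Pecam1 (0.81, SE 0.15) rose, and the scavenger receptor of sinusoidal cells Stab2 fell (-1.29, SE 0.24). Camera gave adjusted p = 2.41e-06 for the hepatoblast and 0.0272 for the endothelial list, against adjusted p = 0.537 for each with an estimated correlation. With sex as a covariate 1 of the 26 hepatoblast genes rose, without wild type 2, 15 or 17 or E861A 6, 16 or 19 these were 7, 4, 3, 4, 2 and 16, and the endothelial call was lost without wild type 2, wild type 17, E861A 16 or E861A 19 (camera adjusted p from 0.0649 to 0.106).

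Lists of blood cell types other than red cells did not pass camera with all 6 libraries and no covariate. With sex as a covariate the stem, granulocytic and megakaryocyte lists passed upward (camera adjusted p = 0.0276, 0.00543 and 5.09e-05; medians 0.55, 0.58 and 0.68), as they did in the male libraries alone (0.0171, 0.00288 and 0.000124). Of 26 stem and progenitor genes 5 rose and none fell (7 when adjusted over the list alone; median 0.01, camera adjusted p = 0.241). The largest rises among them were in Ly6a (6.47, SE 0.26; 1.13 to 100.4 CPM) and Ly6e (3.14, SE 0.21), both also known as interferon targets, and Esam rose by 1.03 (SE 0.16). Of 21 macrophage and monocyte genes 6 rose and 1 fell (7 and 3 when adjusted over the list alone; median 0.13, adjusted p = 0.630). They included the Fc receptor gene Fcgr1 (2.54, SE 0.17), which interferon is known to induce, the adaptor Tyrobp (1.24, SE 0.19) and Hmox1, which the haem list also holds. Of 14 granulocytic genes 3 rose, Prtn3 (1.32, SE 0.31), Ctsg (1.70, SE 0.42) and Cebpa (0.67, SE 0.18), and none fell (4 rose and 1 fell when adjusted over the list alone; median 0.06, adjusted p = 0.641). None of 15 megakaryocyte genes passed, over all genes or when adjusted over the list alone (median 0.23, adjusted p = 0.709). Gp9 (0.54, SE 0.26), Gp1bb (0.58, SE 0.29) and Pf4 (0.64, SE 0.32) had the smallest p. Of 9 lymphoid genes the kinase gene Lck rose from 5.16 to 20.7 CPM, the recombinase gene Rag1 fell (-2.54, SE 0.60) and Cd79b did not pass (0.75, SE 0.28), with the same counts when adjusted over the list alone. The median of the lymphoid list was -0.23 and its camera adjusted p 0.805, with fry pointing up where camera pointed down. None of 15 mesenchymal and stellate cell genes passed either way (median 0.09, camera adjusted p = 0.749), led by Ngfr (0.70, SE 0.46), Hand2 (0.72, SE 0.55) and Des (0.62, SE 0.49). The mesenchymal median turned to -0.45 with sex as a covariate (camera adjusted p = 0.0232) and to -0.44 in the male libraries alone. With single libraries left out it ranged from -0.27 to 0.83 (camera adjusted p from 0.104 to 0.921), so its direction is not settled. Each of the named stem, granulocytic, endothelial and hepatoblast genes except Ly6a, Ly6e and Cebpb lost its edgeR call in at least 1 fit with a library left out, with sex as a covariate or in the male libraries alone.

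Of 16 genes of RNA editing and double-stranded RNA binding 2 rose and 3 fell, over all genes and when adjusted over the list alone (median -0.14, mean 0.03, camera adjusted p = 0.167). The cytidine deaminase gene Apobec1 rose (2.78, SE 0.23), and the genes of the microRNA-processing nucleases Drosha (-0.65, SE 0.13) and Dicer1 (-0.78, SE 0.17) fell, the last 2 only without sex in the model. With single libraries left out the edgeR adjusted p reached 0.116 for Drosha and 0.126 for Dicer1. Adarb1, the gene of the other active adenosine deaminase, stood at 10.2 ± 2.05 CPM in wild type and 9.08 ± 1.78 CPM in E861A (-0.16, SE 0.23) and did not pass. A set of 176 genes holding a site with less editing in E861A had a median of -0.21, with 11 rising and 28 falling (13 and 36 when adjusted over the list alone). Over the 956 genes holding any tested site the median was -0.12, with 39 rising and 72 falling (38 and 70 when adjusted over the list alone). Camera gave adjusted p = 0.000117 and 0.00045 for these sets, against adjusted p = 0.537 for each with an estimated correlation, and both were chosen on these samples and are not independent evidence of direction. Of the 176 genes, 39 fell without wild type 2, 8 without wild type 15, 3 without wild type 17, 3 without E861A 16 and 1 with sex as a covariate. Fry, which asks whether the genes of a list move one way on balance, gave Benjamini-Hochberg adjusted p = 0.000272 for the interferon-stimulated genes, 0.000638 for the p53 list, 0.00239 for interferon induction, and 0.00725 for the stress list. Its adjusted p was 0.0407 for the cell cycle, hepatoblast, macrophage and dissociation lists, 0.0291 for the stem list, 0.0797 for the erythroid, 0.173 for the haem and 0.0815 for the endothelial list.

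Editing was lower in each E861A liver than in each wild-type liver. Over 3883 tested sites the mean editing level was 8.70 ± 1.75% in wild type and 2.18 ± 0.09% in E861A (SD, n = 3 each). By library it was 6.84%, 10.3% and 8.93% in wild type 2, 15 and 17, and 2.08%, 2.20% and 2.26% in E861A 6, 16 and 19. A two-sided exact permutation test gave p = 0.10, the smallest that 3 libraries against 3 allow. On reads summed per genotype, 647 sites in 221 genes were lower in E861A and 6 were higher (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05), and 3230 did not pass. The 647 lower sites had a median level of 14.3% in wild type and 0% in E861A, over a median of 154 and 153 reads, and 451 of them had no edited read in E861A. Of 1059 sites at 10% or more in wild type, 418 were lower, 20 stood at 90% or more in both genotypes and 621 did not pass. By the authors' labels, 161 of 2919 sites known only from before were lower (5.5%). Of sites known before and also found in these samples 343 of 580 were lower (59.1%), and of those found only in these samples 143 of 384 (37.2%). Sites found in these samples were chosen on the same reads, so the counts and mean levels are not independent of that choice.

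**Figure D4:**
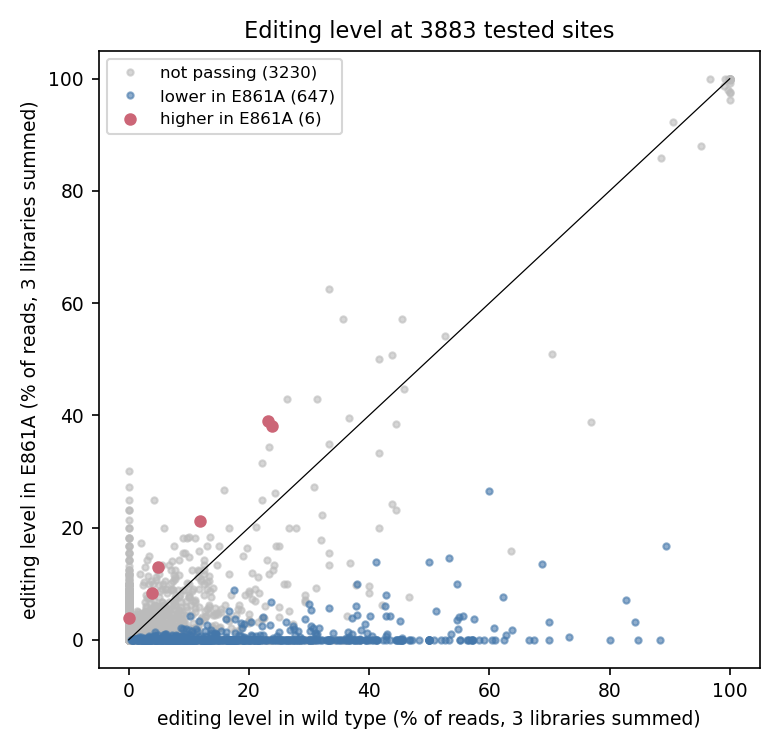
Editing level (% of reads, 3 libraries summed) at each of 3883 tested sites, wild type on the horizontal and E861A on the vertical axis, with the line of equal level. The 647 lower sites (blue) lie along the horizontal axis, the 6 higher sites (red) above the line, and 20 sites at 90% or more in both genotypes in the upper right corner.

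At the sites with the largest differences most reads were edited in wild type and few or none in E861A, on reads summed per genotype. In the 3' untranslated region of Mad2l1, a spindle checkpoint gene, the adenosine at chromosome 6, position 66490075 (plus strand, with 10 bases on each side AATGTGTGTTATTGTTCCATT), was edited in 413 of 612 reads in wild type (67.5%, 95% Wilson interval 63.7 to 71.1%) and in 0 of 348 in E861A, which allows a level of up to 0.86%. In the 3' untranslated region of Rbm8a (chromosome 3, 96436383, plus strand) the level went from 73.3% (67.4 to 78.4%, 247 reads) to 0.51% (0.09 to 2.82%, 197 reads). In that of C330018D20Rik (chromosome 18, 57116216, minus strand) it went from 84.3% (76.0 to 90.1%, 102 reads) to 3.10% (1.21 to 7.70%, 129 reads). Intronic sites fell at Gm5512, inside an intron of Rmnd1 in the annotation used here (chromosome 10, 5918284), from 88.5% of 52 reads to 0 of 55, and at Tbccd1 (chromosome 16, 22854516) from 84.8% of 46 reads to 0 of 12. Further ones fell at Diap3 (chromosome 14, 87311908) from 80.0% of 10 reads to 0 of 15, at Snrnp40 (chromosome 4, 130049566) from 89.5% of 19 reads to 16.7% of 12, and at Nek4 (chromosome 14, 31790141) from 70.0% of 10 reads to 0 of 24. Single libraries departed from this at Nek4, where wild type 15 stood at 0%, and at Snrnp40, where wild type 2 and E861A 19 both stood at 33.3%. The other 2 of the 10 largest differences were in a transcript of Zfp783 (chromosome 6, 47897520; 82.8% of 29 reads to 7.14% of 42) and between genes (chromosome 2, 162873266; 70.0% of 20 reads to 3.23% of 31).

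By the authors' annotation the lower sites lay mainly outside coding sequence. In 3' untranslated regions 422 of 1688 tested sites were lower, in introns 113 of 1485, between genes 79 of 444 and in non-coding RNAs 16 of 89. Of sites that change an amino acid 3 of 83 were lower, and of synonymous sites 0 of 25. The median wild-type level was only 0.25% and 0.14% at these coding sites, so many had little editing to lose. It was 2.37% in 3' untranslated regions, 5.63% in introns, 8.19% between genes and 5.56% in non-coding RNAs. Rpa1 held 28 lower sites, Mad2l1 26, C330018D20Rik 21, Rnf168 21, Wdr76 17 and Ankrd28 16. The long 3' untranslated duplexes of Klf1, Oip5 and Optn, genes taken from earlier work on this mutant, held 17 tested sites, 11 of them lower (15 when adjusted over the list alone). All 5 in the autophagy receptor gene Optn were lower, the best covered (chromosome 2, 4942084) going from 10.2% of 226 reads to 0 of 493, which allows up to 0.61%. In Oip5 4 of 6 were lower, the best covered (chromosome 2, 119435817) going from 7.48% of 468 reads to 0.17% of 589, and in the erythroid factor gene Klf1 2 of 6 were lower.

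Most known recoding sites did not pass the test. The list had 55 tested sites in 11 genes, of which 2 were lower and 4 higher in E861A (6 when adjusted over the list alone) and 49 did not pass. The values of the next 4 sites were seen before they were chosen. The site of Blcap at chromosome 2, 157383885 went from 24.6% of 187 reads to 0.75% of 133 and that of Cdk13 at chromosome 13, 17896178 from 39.5% of 38 reads to 0 of 15. Those of Igfbp7 at chromosome 5, 77836756 (52.6% of 38 reads and 54.1% of 61) and 77836808 (45.5% of 11 reads and 57.1% of 35) did not pass, and at the first of them single libraries ranged from 0% to 68.2% in wild type and from 11.1% to 81.8% in E861A. By the rule fixed beforehand, the best covered site of Cog3, which encodes a Golgi protein (chromosome 14, 76119526), stood at 24.4% of 287 reads in wild type and 26.2% of 275 in E861A. Those of Flna (X, 71472208), Son (16, 91655667), Copa (1, 174022449), Tmem63b (17, 45799898), Ube2o (11, 116442451) and Blcap (2, 157383846) were at 3.12% or less in both genotypes, none passing.

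The higher sites were named after the test. In the filamin gene Flna the recoding site at X, 71472201 (minus strand, TCTAGTCTTCAGGTGAGGCAC with 10 bases on each side) rose from 3.91% (3.07 to 4.97%, 1612 reads) to 8.26% (7.10 to 9.60%, 1864 reads), and the neighbouring sites at 71471988 and 71471989, intronic per the authors, from 4.85% to 12.98% and from 23.9% to 38.2% over 206 to 262 reads. Further ones were in the 3' untranslated region of Ankrd28 (14, 32514637; 0 of 207 reads to 3.95% of 177) and at chromosome 19, 61259060 (23.1% of 134 reads to 39.0% of 123). At each of these 5 sites each E861A library lay above each wild-type library.

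**Figure D5:**
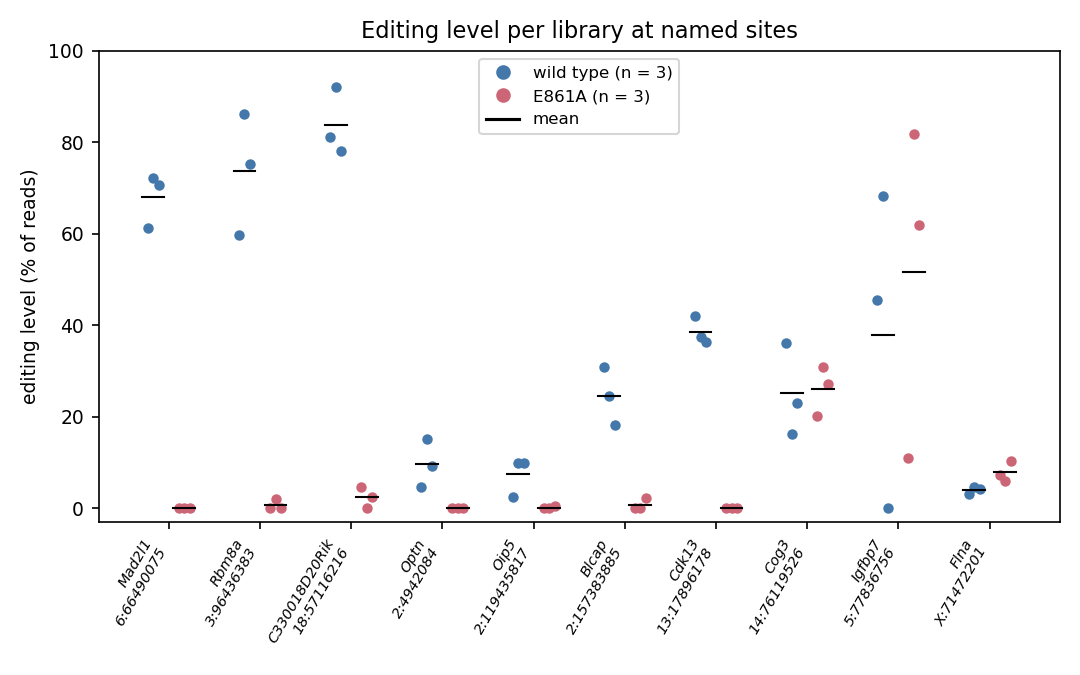
Editing level (% of reads) per library at named sites, wild type in blue and E861A in red, with a black line at the mean of 3 libraries. Mad2l1, Optn and Cdk13 stand at 0% in each E861A library, with 15 E861A reads in all at Cdk13. Cog3 overlaps between the genotypes, and each E861A library lies above each wild-type library at the Flna site.

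Fisher's test compares the summed reads of each genotype and not the spread between libraries. A quasi-binomial model across libraries, with a dispersion for each site, left 0 sites lower and 0 higher after adjustment (652 lower and 6 higher at an unadjusted p under 0.05). With 1 dispersion shared by all sites, added after that result, 462 sites were lower and 1, the Flna site at 71472201, was higher. Of 1406 sites with a p in the authors' deposited table, 323 were lower and 7 higher in E861A at a p under 0.05. The mean levels there, as a fraction, were 0.0627 in wild type and 0.0157 in E861A.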

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

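The covariates for embryo number, mesenchymal level and dissociation level, the minimum of 10 reads in every library, the exclusion of sites at 90% or more in both genotypes and the shared dispersion were chosen after the result was seen, and the other settings beforehand. The genes changed between E861A and wild type were 569 (530 rose, 39 fell) with sex as a covariate instead of 1986, and with male libraries only 309 (301 rose, 8 fell). More genes fell, 1160 and 1388 instead of 703, when genes needed 1 CPM in 3 libraries or with DESeq2. With single libraries left out the total ranged from 650 to 3239, the rises from 515 to 1737 and the falls from 95 to 1502. All 703 falls kept their sign with sex in the model, with male libraries only and with DESeq2. At 1985 of the 1986 changed genes the libraries of the genotypes did not overlap, so these signs were all but fixed and add no support. With the estimated correlation the interferon-stimulated list kept its median of 5.38 but had an adjusted p of 0.221 (medians of 5.26 to 5.57 with single libraries left out). The mesenchymal median reversed to -0.45 with sex (camera adjusted p 0.0232) and -0.44 with male libraries only, from 0.09, and ranged from -0.27 to 0.83 with single libraries left out. The difference in editing level moved from 6.52 points to 19.21 over sites at 10% or more in wild type and to 4.73 over sites with 10 reads in every library, and was 5.55 to 7.13 with single libraries left out. Instead of 647 lower and 6 higher sites, the planned quasi-binomial model gave 0 and 0 and the shared dispersion 462 and 1. Sites at 10% or more in wild type gave 3 higher ones, and with single libraries left out 473 to 679 sites were lower and 3 to 8 higher. Of the values of named genes over all settings, 1254 stayed the same, 160 were weaker, 14 stronger and none reversed, and the settings with the most weaker ones were male libraries only (33) and sex (29). A restriction to A-to-G sites was not run, as the table holds 0 other substitutions. Possible causes of the fewer falls with sex in the model or male libraries only are weighed below, and the cause of the other shifts was not tested.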

Other observations

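The gene families, the window around Adar, the neighbouring bases and the sites near 100% were chosen after the result was seen, as were the tests below of sex, embryos 2 and 6, library scaling, the other cell types, Flna and Adarb1, and the count of genes in other splits. What the mesenchymal level, the dissociation level, the expression of genes that lost editing, and the counts of lists and of sites in other splits would show was written down before they were computed.

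Fewer genes fell once sex was in the model or only male libraries were used (39 and 8, against 703), which could come from sex, from a batch shared by embryos 2 and 6, or from the share of mesenchymal cells. Over the 703 falls E861A 6 differed from E861A 16 and 19 by a median of 0.05 log2 CPM, but these genes were chosen for alike E861A libraries, and the dissociation list was lowest in embryos 2 and 6 within their genotypes, so a batch is not excluded. With sex in the model the median of the falls was -0.59 (median SE 0.19) instead of -0.86 (median SE 0.18), and a single male wild-type liver cannot tell a sex difference from a peculiarity of that liver. The mesenchymal level as a covariate gave 853 falls, as written beforehand for that explanation, but embryo number (983) and dissociation level (1017) as covariates also gave more, so the result does not single it out. It stays open how many of the 703 falls belong to the genotype.

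Erythroid, haem and cell cycle genes fell while hepatoblast genes rose, which could come from library scaling, from dissociation, or from fewer erythroid cells among otherwise alike cells. The erythroid median was -0.92 with library totals alone, against -1.01 with TMM factors, so the choice between these scalings does not account for the fall. A bias that both scalings share could not be tested in this way. With the dissociation level as a covariate the median was -1.32, which met what was written beforehand against dissociation. The fall did not shrink, but each E861A library lay above each wild-type library in that level. The genotypes were therefore not compared at alike levels, and dissociation is not excluded. Hepatoblast genes lay 0.59 above the 91 genes of 5 other cell lists (95% interval 0.33 to 0.80 over 10000 bootstrap draws of genes). This met what was written, after the result was seen, against a simple loss of erythroid cells. The interval treats genes as independent and holds no spread between livers. Per library the difference in mean log2 CPM between these genes was between 2.94 and 3.04 in the wild-type livers. It was 3.41, 3.74 and 3.02 in E861A 6, 16 and 19, so the genotypes overlap. Dissociation, and whether cells were lost or genes changed within cells, stay open, since whole livers were sequenced.

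Sites of Flna were edited at higher levels in E861A, which could rest on reads of 1 library, on more Adarb1, or on a different mix of cells. At the recoding site (X, 71472201) the largest Fisher p with any library left out was 0.00154, which argues against a single library, whereas at 71471988 and 71471989 it was 0.269 and 0.0637, both without wild type 2. Adarb1 mRNA had a log2 fold change of -0.16 (SE 0.23) with an upper limit of 0.48, only just under the bound of 0.5. Flna mRNA did not pass (-0.19, SE 0.26). A different mix of cells stays open, as 3 libraries per genotype cannot test it.

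Loss of editing may go with slightly lower expression of the same gene: the 176 genes with a lower site had a median log2 fold change 0.11 lower (difference -0.11; -0.21 against -0.10) than 780 genes with tested sites and none lower, with a two-sided permutation p of 0.0086 over 100000 permutations of genes. The difference was -0.08 with sex in the model and -0.12 log2 CPM in the real split, against at most 0.10 in either direction in the other 9, a condition added after the p was seen. Genes are not independent of each other in 6 libraries, and the set was chosen on these samples.

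Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.1. For genes changed, 1 of the 10 splits, the real one, reached 1986, and the highest other gave 0. For sites lower in 1 group, 1 of the 10, the real one, reached 647, and the highest other gave 267. For gene lists, 3 of the 10 reached 12, and the highest other gave 12. The other splits with 12 lists put wild type 2 and E861A 6 together, with wild type 15 or with E861A 16. The interferon-stimulated list passed camera in all 10 splits, but its median was 5.38 in the real split and at most 1.25 in the others. The erythroid median was 1.01 in size against at most 0.87, the cell cycle median 0.62 against 0.55, the p53 median 0.97 against 0.45, and the mesenchymal median 0.09 against 1.08.

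In a further comparison, 267 groups of genes sharing the stem of a symbol were set against all other genes. One-sided Fisher's exact tests were used, for rises and for falls apart, treating genes as independent. Each direction had its own Benjamini-Hochberg adjustment over the groups. The groups overlap the fixed lists: 2 Gbp, 2 Schlafen, 2 Trim and 3 Parp genes are on the interferon-stimulated list, and Trim10 is on the erythroid list. All 10 guanylate-binding protein genes rose (adjusted p 2.07e-09), led by Gbp3 (7.10, SE 0.39) and with Gbp7 (5.31, SE 0.29). Of 24 major histocompatibility genes 14 rose (3.41e-08), among them H2-D1 from 60.1 to 668.2 CPM and H2-K1 from 68.9 to 687.7 CPM. Also 8 of 9 Schlafen genes rose (7.28e-07), with Slfn4 at 8.76 (SE 0.28), 19 of 55 Trim genes (7.28e-07; 4 fell, among them Trim10 at -1.52), 8 of 12 Ccl genes (1 fell, Ccl24) and 8 of 12 Parp genes (2 fell; 1.85e-05 each). Many of these genes have near-identical copies, which leaves single values uncertain.

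Among the falls, 9 of 36 kinesin genes (adjusted p 0.0028), 6 of 15 genes of the mitochondrial genome (0.0028) and 9 of 47 Usp genes (0.0124) were lower by the same Fisher's exact test, while 1 gene of each group rose. Of the mitochondrial genes, mt-Nd1 went from 2722 to 1263 CPM, while the ribosomal RNA mt-Rnr1 rose from 310 to 1080 CPM. The mitochondrial median was -0.45, -0.50 with DESeq2 size factors and -0.37 with library totals. With sex in the model 1 mitochondrial gene fell and none rose. Of 273 genes within 10 Mb of Adar 22 rose and 8 fell, a share like that elsewhere (two-sided Fisher's exact p = 0.82 and 0.362).

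A G stood before the edited adenosine at 3.6% of the 647 lower sites. The share was 2.4% of 123 sites between 10% and 90% in wild type, at least 5% in E861A and not called lower. These include sites called higher, such as Flna at X, 71471989. Of 626 sites under 1% in both genotypes it was 24.3% (Fisher's exact p = 4.24e-29 against the lower sites). Some of the 123 had few reads and a large drop, such as Tex9 from 63.6% of 11 reads to 15.8% of 19. A G stood after the adenosine at 35.9%, 52.0% (p = 0.00115) and 46.2% (p = 0.000209) of these sets by the same Fisher's exact test. Deaminases of this family are known to disfavour a G before and to favour a G after the site. Against the sites under 1% in both genotypes, the lower sites had a G less often on either side. Adenosines outside the listed sites were not counted, so these shares do not measure a preference over the background. At the 20 sites at 90% or more in both genotypes a G stood before 5, and 6 of 18 with a known strand lay on the strand opposite to the gene (33.3%, against 2.4% of lower sites). Without these 20 sites 650 sites were lower and the mean level was 8.22% in wild type and 1.68% in E861A.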
